A study of Mus musculus with 2 samples.

How the data were processed

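The data are 2 microarrays of mouse messenger RNA, 1 from germ-free mice, which are raised without any microorganism, and 1 from specific pathogen-free mice, which carry a gut microbiota but no listed pathogens. Per the labels, the RNA came from mononuclear cells isolated from the colonic lamina propria, the connective tissue under the gut epithelium, of male Balb/c mice. The labels do not say how many animals contributed to each array. The arrays were of the Toray 1-colour design: amplified amino allyl RNA was coupled to Cy5 and read at 635 nm. Samples were placed in groups by their titles, with 1 array in each group, and no array was left out.

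Per the file headers, each scanner file holds the median intensity of every spot and of its local background at 635 nm, combined from scans at 3 gains, with no background subtracted and no normalization. Each array had 27456 spots, of which 23474 carried a probe for a transcript (23473 different probes), 384 were empty BLANK spots, 96 were negative and 48 positive controls, and 3454 were positions with no probe. The authors also deposited a table of processed intensity values. Set against the scanner values, each column of that table was a straight line of the spot median: the trimmed mean of the array's BLANK spots was subtracted and the result multiplied by 1 factor per array, so that the median value was 25. All 19579 (germ-free) and 19712 (specific pathogen-free) values compared lay within 0.06 of that line. The table is linear, not centred by gene, and empty for probes not above the BLANK spots (3893 on the germ-free and 3760 on the specific pathogen-free array). The scanner, the image software and the program that made the table are not given in the sources used here.

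Signals called the authors' signals are from that deposited table, averaged over the probes of a gene. Log2 differences and folds were computed from the scanner files. The spot medians were corrected with limma's normexp method with an offset of 50, fitted on all spots without the local background column, because that column tracked the spot signal itself (correlation of the logs across spots 0.898 and 0.906). The choice to leave the local background column out was made after this correlation was seen. Control spots and 19 probes with a spot marked as bad on either array were then left out. Log2 values were quantile normalized between the arrays, spots of 1 probe were averaged, and then probes of 1 gene. The offset shrinks the folds of dim genes, so that the ratio of the authors' signals is often larger than the fold given. A probe counted as detected when its spot median lay over 2 SDs above the mean of the BLANK spots, both after trimming 5% at each end (limits of 61.5 and 61.9 intensity units). This rule matched the filled and empty cells of the deposited table for 23432 and 23455 of 23472 probes. Detected probes made up 83.4% of probes on the germ-free and 83.9% on the specific pathogen-free array. For a gene detected on 1 array only, the other side was set to the higher of its own value and the lowest detected level, and the fold is given as a bound.

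Probe names came from the platform annotation: 20690 probes had 1 gene symbol, 0 had several and 2783 were not listed and stay unnamed here. Of the named probes, 20556 matched a current gene through their Entrez identifier, and 0 symbols needed updating. The named probes covered 19308 genes, 1281 of them with more than 1 probe. No genome was used, so no coordinates are given.

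With 1 array per group there is no spread between animals, so the difference between the groups was not tested and no p-value or standard error is given. Genes were counted by a fixed size, at least 2-fold (1 or more on the log2 scale) in either direction. The 33 gene lists were fixed before the data were examined. So were the other choices, except leaving out the local background column and those named as made later. For each list, the median log2 difference of the detected members was placed among the medians of 10000 random gene lists. These had the same size and were matched on mean level in 20 bins. A list is described as standing apart at or below the 2.5th or at or above the 97.5th percentile, and lists with under 5 detected members have values only. The percentile describes these 2 arrays and is not a test across animals. In the closing section, explanations by the share of a cell type were weighed by the gap between the medians of list pairs, with a 95% bootstrap interval from 10000 resamplings of the genes in each list, under the main values, without the offset and with the deposited values, each with all genes and with genes whose mean signal was at least 25. An explanation was held to be excluded by a gap only where all 6 intervals lay on the side of 0 that it forbids, a rule set after the gaps were seen. These intervals describe the spread of genes, not of animals. Of 599 list genes, 547 were found among the named genes.

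Genes are named in the text by a rule with 4 parts. It takes the 10 largest differences in each direction among genes detected on both arrays with levels above their median, and the 3 largest bounds in each direction among genes detected on 1 array only. It also takes up to 3 members of each list with the largest differences, and genes fixed by name, of which Il2, Bcl11b, Ets1, Zeb1, Zeb2, Foxp3, Epcam, Cdh1, Ptprc, Cd3e and Reg3g are reported here. Some further list members are named as examples and were chosen after their values were seen.

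The calculation was tested on simulated arrays of 17157 genes for the germ-free against specific pathogen-free comparison, with noise of 0.25 (SD, log2). True changes of 4-fold were counted as at least 2-fold for 94% of 50 genes, 3-fold for 66%, 2-fold for 16% and 1.5-fold for 0%. Of 16937 unchanged genes, 9 were counted (0.0531%). The changed genes were drawn from genes with a mean signal at least 50 intensity units above the BLANK spots. The noise was a set value and held no difference between animals or in the mix of cells. These rates therefore do not cover changes of dimmer genes or differences between samples. Other background corrections, offsets, scalings, filters, probe rules, size thresholds and the deposited table itself were tried as alternatives. A correction that uses the local background column, and a detection limit at the 97.5th percentile of the positions with no probe, were added after seeing the data. Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.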

Results

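Messenger RNA was profiled in colonic lamina propria mononuclear cells, the mixed immune cells isolated from the tissue under the colonic epithelium, from germ-free and from specific pathogen-free male Balb/c mice, with 1 array for each. The series is the messenger RNA part of a study that also measured microRNAs in these cells, and the comparison asks whether the gut microbiota alters the levels of transcripts, among them targets of microRNAs. The median spot intensity was 84.4 on the germ-free and 88.6 on the specific pathogen-free array, against trimmed means of 58.7 and 59.6 for empty BLANK spots. The number of arrays limits the precision: there was no replicate, so every difference given is between 2 arrays and has no replicate check. As a technical guide only, the log2 differences from separate probes of 1 gene had an SD of 0.235 over 896 genes with 2 detected probes. That SD is over all of these genes, most of which differed little. In 31 of them at least 1 probe reached 2-fold, and both probes went in 1 direction for only 23 of the 31. For 0 of the 31 were the probes at least 2-fold in opposite directions.

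On the germ-free array, interferon-induced genes and T cell genes were higher. Trim30a was 6.18-fold higher, Ifit1, an antiviral protein that binds foreign RNA, 5.20-fold, and Cd8b1, a chain of the CD8 co-receptor, 4.06-fold. On the specific pathogen-free array, epithelial, antibody and cell division genes were higher. Cdh1, the epithelial adhesion protein E-cadherin, was 3.81-fold higher there, the antibody light chain segment Igkv7-33 23.0-fold, and Mki67, a marker of dividing cells, 3.27-fold.

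Of 16870 genes detected on at least 1 array, 154 (0.913%) were at least 2-fold higher on the germ-free array and 326 (1.93%) were at least 2-fold higher on the specific pathogen-free array. The other 16390 differed by less. The median log2 difference, germ-free minus specific pathogen-free, was 0.02 with an SD of 0.37 across genes, and log2 levels on the arrays correlated across genes at r = 0.964 (genes are not independent replicates). Germ-free-higher genes made up 32.1% of those counted, and 19.8% with median scaling (106 against 429 genes). With 75th percentile scaling the median of all genes was 0.12, to be subtracted when values are read under that scaling. Without the normexp offset the counts were 411 and 948, and 798 and 1241 with the deposited values. The plot of levels on the arrays shows both sets of genes against the bulk.

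**Figure D1:**
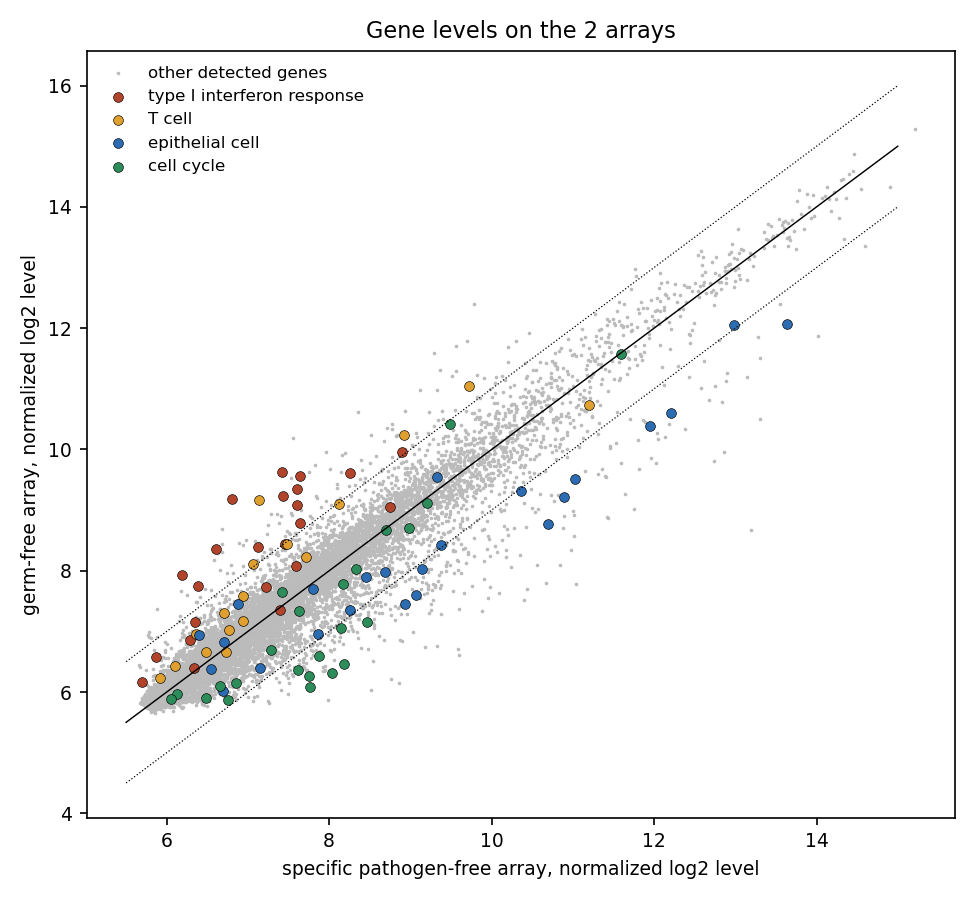
Normalized log2 level of each detected gene on the specific pathogen-free array (x axis) and the germ-free array (y axis), 1 array per group, with 4 gene lists coloured. The solid line marks equal levels and the dotted lines 2-fold differences. Of the type I interferon genes, 13 of 23 lie at or above the upper dotted line, and 10 of 24 epithelial genes lie at or below the lower one.

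Among genes with levels above the median, the 10 largest differences toward germ-free were Trim30a, Ifi47, Ifit1, Ms4a4b, Ifi209, Mx2, Igtp, Trib2, Cd8b1 and Slfn1. The authors' signal of Ifi47, an interferon-induced GTPase, was 2954 on the germ-free and 508 on the specific pathogen-free array (6.11-fold). Ms4a4b, a T cell membrane protein, had 1593 against 353 (4.89-fold). Toward specific pathogen-free the 10 were Igkv7-33, Sprr2a2, Gsdmc, Ighv7-1, Igkv1-135, Sprr2b, Gsdmc2, Igkv5-48, Igkv8-30 and Muc3. Igkv7-33 had a signal of 196 on the germ-free and 5353 on the specific pathogen-free array. Sprr2a2, a small proline-rich protein of epithelial cells, was 9.59-fold higher, Gsdmc, a gasdermin, 7.87-fold, and Muc3, a membrane mucin, 6.69-fold. Antibody segments, Sprr2 genes and gasdermin C genes are families of similar sequence, so a probe may read more than its own gene and their single-gene values are uncertain. Of genes detected on the germ-free array only, the largest bounds were at least 2.29-fold for Defa17 and 2.20-fold for Defa24, which encode Paneth cell defensins of near-identical sequence, and 2.16-fold for Cyp2e1. Of those detected on the specific pathogen-free array only, they were at least 1.62-fold for Cldn8, 1.57-fold for Cxcl5 and 1.54-fold for Cav2.

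Genes of the type I interferon response, the antiviral programme, were higher on the germ-free array as a group: 13 of 23 measured members were at least 2-fold higher there, 0 were at least 2-fold lower and 10 lay between. Their median log2 difference was 1.16, above all 10000 matched random lists (percentile 100). Mx2, a dynamin-like antiviral GTPase, was 4.65-fold higher, with signals of 408 and 70.5, and Xaf1 3.81-fold. In the list of interferon-gamma response and MHC class II genes, 4 of 25 were at least 2-fold higher on the germ-free array and 21 lay within 2-fold (median 0.40, percentile 100). The 4 were Igtp (4.46-fold), Gbp2 (3.62-fold), Irgm1 (2.75-fold) and Gbp4, all GTPases of the cell's own defence against intracellular microbes; none is an MHC class II gene. T cell markers moved the same way on these arrays, with a median of 0.60.

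T cell markers were higher on the germ-free array: 4 of 17 by at least 2-fold, 0 lower by that much and 13 between (median 0.60, percentile 100). Cd8b1 had signals of 289 and 52.6, and Cd3d and Cd2, T cell surface proteins, were each 2.5-fold higher. Cd3e was dim, at 18.9 and 9.0, and 1.25-fold higher. Ptprc, the leukocyte marker CD45, was 1.74-fold higher, but its log2 difference was -1.74 when the local background column was used in the correction. Of the T cell activation genes, 0 of 19 reached 2-fold in either direction, with a median of 0.36 (percentile 99.99). Cd69, an early activation marker, was 1.76-fold and Nr4a1 1.74-fold higher on the germ-free array, and Il2 went the other way. This list was at percentile 88.6 when the local background was used.

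The regulatory T cell list did not stand apart (median 0.03, percentile 44.3; 1 of 13 genes at least 2-fold higher on the germ-free array). That gene was Ikzf4, at 2.15-fold, whereas Foxp3, the defining factor of these cells, had signals of 37.1 and 36.5. In the list for type 17 and group 3 innate lymphoid cells, 1 of 12 genes, Batf, was at least 2-fold higher on the germ-free array (2.08-fold, but under 2-fold with median or 75th percentile scaling or with the local background), and Il17f was 1.82-fold higher on the specific pathogen-free array (median -0.08, percentile 11.5). Type 1, natural killer and cytotoxic genes had 0 of 17 past 2-fold (median 0.06, percentile 70.2), with Tbx21, a type 1 lineage factor, 1.62-fold higher on the germ-free array. In the type 2 list, 1 of 9 genes passed 2-fold: Il5, the eosinophil growth factor, was 2.62-fold higher on the specific pathogen-free array, with signals of 149 and 482 (median -0.15, percentile 5.30). B cell genes had a median of 0.09 (percentile 73.2), and 1 of 16, the follicle-homing receptor Cxcr5, was at least 2-fold higher on the germ-free array (2.4-fold).

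Among genes linked to microRNA-200 targets, Zeb1, a transcription factor that represses epithelial genes, was 2.24-fold higher on the germ-free array, with signals of 342 and 150 (probe M200001511). Ets1, a lymphocyte transcription factor, was 2.09-fold higher, at 290 and 133 (M300008034). Bcl11b, which maintains T cell identity, was 1.94-fold higher, at 164 and 75.4 (M200008831). Bcl11b is also in the T cell list, whose median was 0.60 toward germ-free. A larger share of T cells therefore cannot be told apart from a change within cells here. Il2, the T cell growth factor, was 1.88-fold higher on the specific pathogen-free array, at 11.6 and 50.8 (M200003286). Zeb2 was near background on both arrays, at 5.55 and 4.45. Fn1, fibronectin, a member of the fibroblast and smooth muscle list (median -0.46), was 2.63-fold higher on the specific pathogen-free array, but under 2-fold with the local background. As a list of 13 measured genes these went both ways, with 2 at least 2-fold higher on the germ-free array, 1 on the specific pathogen-free array and 10 between, and did not stand apart (median 0.03, percentile 52.9). Il2 is dim on the germ-free array, so its size depends on the offset: its log2 difference was -0.91, and -1.92 with an offset of 0. With median scaling Ets1 and Zeb1 were just under 2-fold (log2 differences of 0.92 and 0.99), and Zeb1 was at 0.47 when the local background was used. The plot of selected genes shows these signals beside the T cell and epithelial markers.

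**Figure D2:**
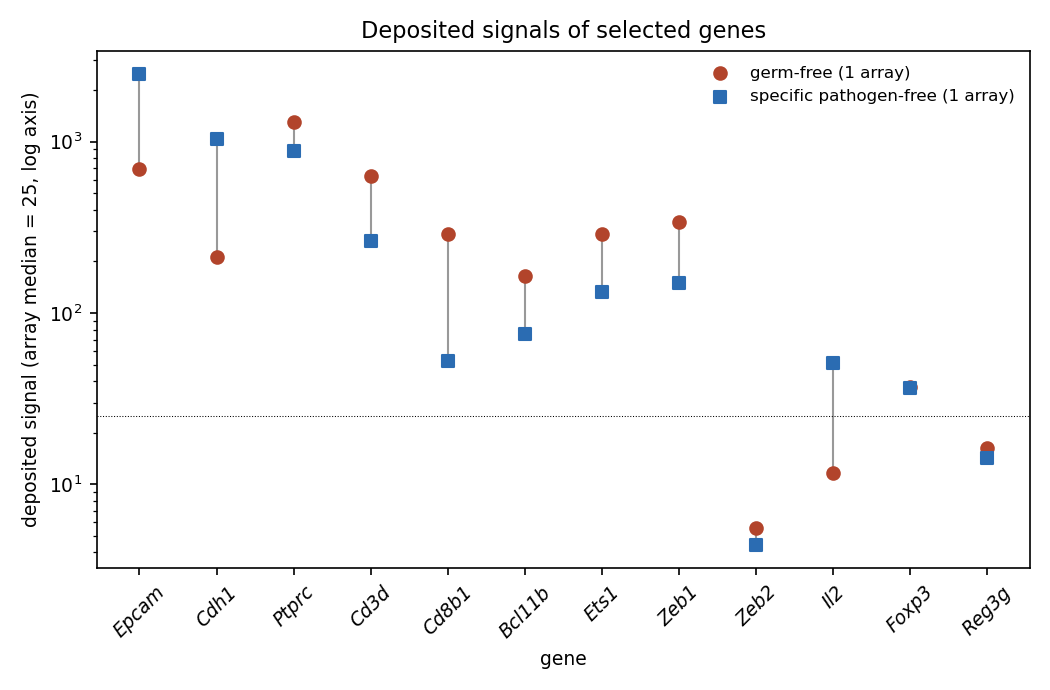
The authors' signals (y axis, log scale, array median set to 25 as marked by the dotted line) of 12 genes on the germ-free array (circles) and the specific pathogen-free array (squares), 1 array per group, so there are no error bars. Cd3d, Cd8b1, Bcl11b, Ets1 and Zeb1 lie higher on the germ-free array, Epcam, Cdh1 and Il2 on the specific pathogen-free array, and Foxp3 has 37.1 and 36.5.

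Epithelial markers were higher on the specific pathogen-free array: 10 of 24 by at least 2-fold, 0 lower by that much and 14 between (median -0.92, below all 10000 random lists, percentile 0.0). Epcam had signals of 696 and 2473 (2.96-fold), and the tight junction protein gene Cldn3 was 3.20-fold higher. Krt19, a keratin, was 3.06-fold higher, but its direction reversed to a log2 difference of 0.69 when the local background column was used. Goblet, Paneth and enteroendocrine genes did not go together. Of 16, 2 were at least 2-fold higher on the germ-free array, Retnlb (3.39-fold, signals 164 and 29.3) and the goblet cell factor Spdef (2.34-fold), and 2 on the specific pathogen-free array, among them Tff3 (2.32-fold); the median was -0.10 (percentile 3.05, or 0.27 with the deposited table). Fibroblast and smooth muscle genes were higher on the specific pathogen-free array, 4 of 19 by at least 2-fold (median -0.46, percentile 0.0). Col3a1, a fibrillar collagen, was 2.52-fold and Acta2, smooth muscle actin, 2.24-fold higher there. With the local background Acta2 and Fn1, also counted here, were under 2-fold. Endothelial, glial and red blood cell genes had 0 of 11 past 2-fold (median 0.05, percentile 84.9), with the endothelial marker Pecam1 1.24-fold higher on the germ-free array.

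Plasma cell genes were higher on the specific pathogen-free array, 3 of 12 by at least 2-fold and 9 between (median -0.36, percentile 0.19). Derl3, which serves disposal of misfolded secretory proteins, was 3.17-fold higher and Tnfrsf17, the plasma cell survival receptor BCMA, 2.27-fold. Pigr, the epithelial carrier of IgA, was 2.01-fold higher, but under 2-fold with the local background. Jchain, Igha, Ighm and Igkc of this list were not among the named genes. Genes of endoplasmic reticulum stress and heat shock had 3 of 19 at least 2-fold higher on the specific pathogen-free array (median -0.38, percentile 0.05). They were Asns (2.62-fold), Chac1 (2.44-fold, but under 2-fold with the local background) and Hsp90b1 (2.0-fold). Cell cycle genes were higher there too, 8 of 24 by at least 2-fold and 16 between (median -0.56, percentile 0.0). Birc5 had signals of 15.4 and 125, Mki67 20.5 and 142, and the cyclin gene Ccna2 8.52 and 99.3. With the local background Birc5 was under 2-fold. Oxidative phosphorylation genes had 0 of 24 past 2-fold, yet 23 of 24 were higher on the specific pathogen-free array (median -0.39, percentile 0.02), with Ndufb8 1.62-fold and Cox5a 1.57-fold higher. On the same arrays the epithelial median was -0.92.

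**Figure D3:**
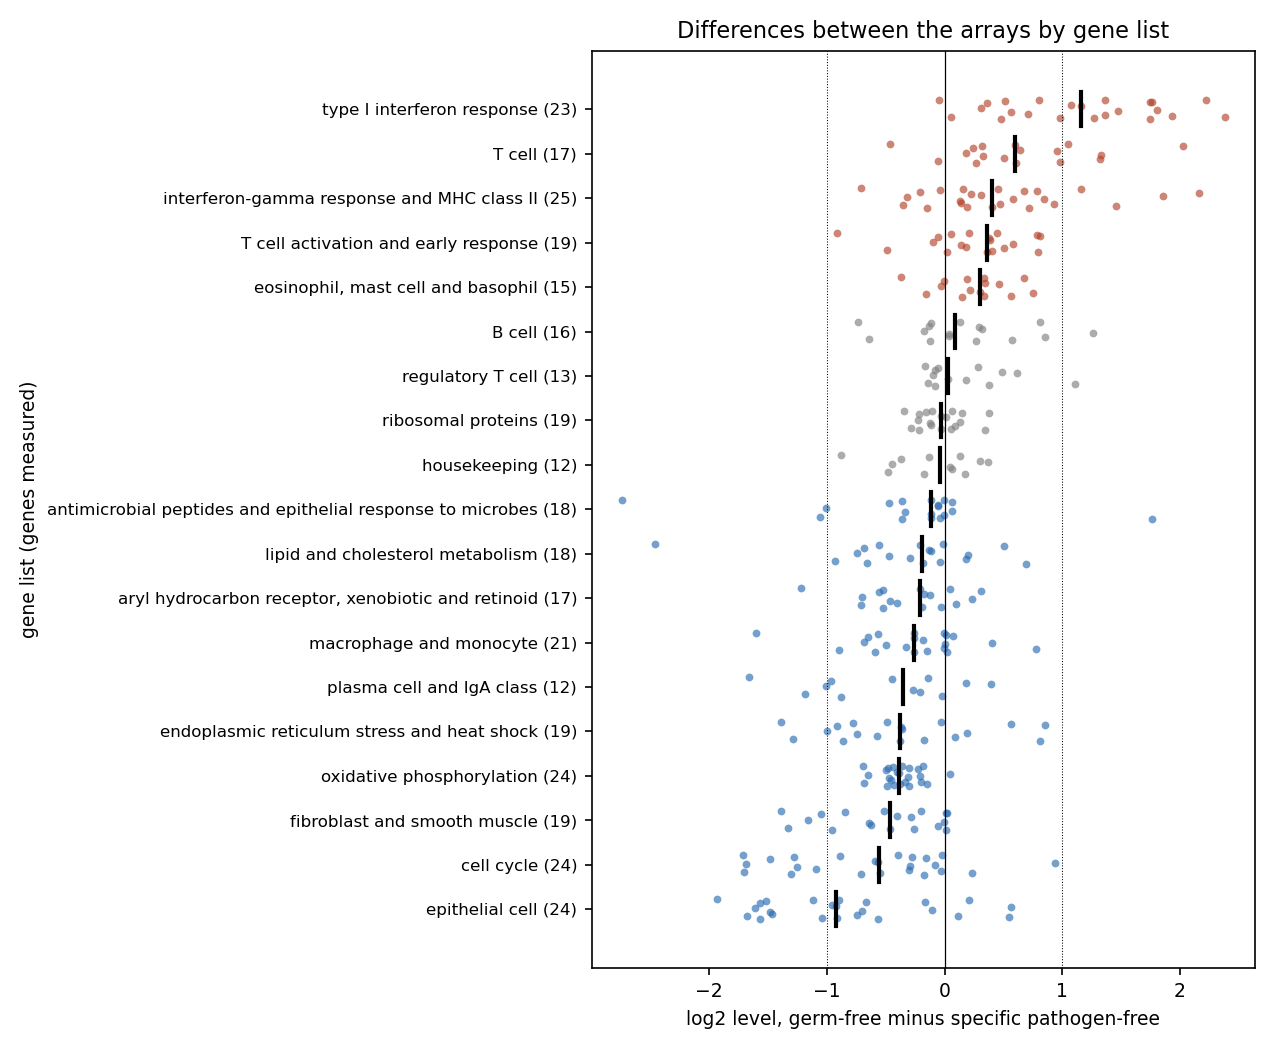
Log2 level on the germ-free array minus that on the specific pathogen-free array (x axis) for each measured gene (points) of 19 gene lists (y axis, number of genes in brackets), 1 array per group. Black bars are list medians, dotted lines mark 2-fold, and colours mark lists that stood apart toward germ-free (red), toward specific pathogen-free (blue) or not (grey). Medians run from 1.16 for type I interferon genes to -0.92 for epithelial genes. That of the antimicrobial list was 0.02 under 75th percentile scaling, where the median of all genes was 0.12.

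Macrophage and monocyte genes were higher on the specific pathogen-free array as a list, although 1 of 21 passed 2-fold (median -0.26, percentile 0.0). That gene was Cd14, the lipopolysaccharide co-receptor, at 93.7 and 379 (3.04-fold); Apoe went the other way, 1.71-fold higher on the germ-free array. For Ly6c2, a monocyte gene, 1 probe gave a log2 difference of -1.88 and the other 0.09. On the same arrays epithelial (median -0.92) and fibroblast markers (-0.46) moved the same way as the macrophage list, and T cell markers (0.60) the other way. Dendritic cell genes did not stand apart (median 0.05, percentile 71.4), but 2 of 16 were at least 2-fold higher on the germ-free array: Ccr7, the lymph node homing receptor, at 1193 and 557 (2.41-fold), and the maturation marker Cd83 (2.05-fold), both under 2-fold with median scaling. Eosinophil, mast cell and basophil genes had 0 of 15 past 2-fold and a median of 0.30 (percentile 99.99), which was 0.03 with the local background; the mast cell genes Tpsb2 and Cpa3 were 1.69-fold and 1.60-fold higher on the germ-free array. In the neutrophil list 1 of 13 genes passed 2-fold, Ly6g, at 30.9 and 325 (median -0.02, percentile 6.20). Toll-like and NOD-like receptor genes did not stand apart (median -0.04, percentile 9.49), with 1 of 14, Cd14, past 2-fold and Tlr2 1.82-fold higher on the specific pathogen-free array.

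Genes for antimicrobial peptides and the epithelial response to microbes had 3 of 18 at least 2-fold higher on the specific pathogen-free array. On the germ-free array 1 was, Retnlb (list median -0.12, percentile 0.18). Under 75th percentile scaling the list median was 0.02, below the 0.12 of all genes. The list came inside the percentile limits with the local background and among genes with levels above the median. Lypd8, an epithelial protein that holds flagellated bacteria away from the mucosa, had signals of 259 and 2191 (6.69-fold). The bactericidal phospholipase gene Pla2g2a was 2.08-fold higher on the specific pathogen-free array. With the local background Pla2g2a and Pigr, also counted here, were under 2-fold. Reg3g, an antibacterial lectin, was dim on both arrays, at 16.3 and 14.3. Inflammatory cytokine and NF-kB target genes did not stand apart (median 0.03, percentile 39.6), but 3 of 23 were at least 2-fold higher on the specific pathogen-free array: Il18, at 12.6 and 233 (5.79-fold), Cxcl2 (2.95-fold) and Ccl20 (2.33-fold). Chemokine and homing receptor genes had 1 of 21 past 2-fold, S1pr1, the receptor that leads lymphocytes out of tissue, which was 2.63-fold higher on the germ-free array, but under 2-fold with the local background (median -0.03, percentile 9.04). The epithelial markers, at -0.92, and the T cell markers, at 0.60, moved on the same arrays.

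The aryl hydrocarbon receptor, xenobiotic and retinoid list had 1 of 17 past 2-fold, Cyp2c55 (2.33-fold, under 2-fold with the local background; median -0.21, percentile 0.03). The lipid and cholesterol list had 1 of 18, the fatty acid desaturase gene Scd2, at 125 and 930 (5.52-fold; median -0.20, percentile 0.49). Both lists lay toward the specific pathogen-free array, where epithelial markers were also higher (median -0.92). Short-chain fatty acid genes did not stand apart (median -0.07, percentile 12.5), with 1 of 9, the butyrate transporter gene Slc5a8, 2.85-fold higher on the specific pathogen-free array. Circadian clock genes did not either (median -0.09, percentile 5.98), with 1 of 15, the repressor gene Nr1d1, 2.5-fold higher there. Ribosomal protein genes (0 of 19 past 2-fold, median -0.03, percentile 21.6) and housekeeping genes (0 of 12, median -0.04, percentile 24.0) did not stand apart, although Pgk1 was 1.84-fold and Gapdh 1.40-fold higher on the specific pathogen-free array. Of 3 measured sex-linked genes, the Y-linked Kdm5d and Eif2s3y had signals of 43.0 and 36.6, and of 244 and 255. In all, 5 lists stood apart toward germ-free and 10 toward specific pathogen-free, of 32 with a percentile. Lists of randomly drawn genes would give 1.6. That number is a guide only, since some lists share genes and markers of 1 cell type may move together between any 2 samples.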

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

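The stricter detection limit given here was chosen after the data were seen. Positions on the arrays that carry no probe gave signal above the detection limit on both arrays: 40.7% of them on the germ-free and 44.3% on the specific pathogen-free array, against 6.25% and 7.29% of the negative control spots. With the limit set from those positions instead, 151 and 326 genes were counted, against 154 and 326.

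Probes without a listed gene also differed. Of 2081 detected on both arrays, 21 were at least 2-fold higher on the germ-free and 33 on the specific pathogen-free array. The largest were M400005934, with signals of 345 and 3303, and M300013112, with 562 and 3663, toward specific pathogen-free, and M400000769 (3.65-fold) and M400000946 (3.55-fold) toward germ-free.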

How the results depend on the processing

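The use of the local background column and the detection limit from positions with no probe were chosen after seeing the data. So was leaving that column out of the main values. The other alternatives were planned. The type I interferon list stayed between 0.94 and 1.72, the T cell list between 0.22 (with the local background) and 1.07, the epithelial list between -1.35 and -0.82 and the cell cycle list between -1.38 and -0.45 under 13 alternatives each. Counts of genes at least 2-fold higher on the germ-free and on the specific pathogen-free array were 696 and 1258 with plain subtraction, 242 and 566 with an offset of 16, 411 and 948 with an offset of 0, and 798 and 1241 with the deposited table. The main 154 and 326 genes were all among them with subtraction and both offsets, and 138 and 326 of them with the table. A threshold of 1.5-fold gave 514 and 865 genes and one of 3-fold 37 and 101. With the local background the counts were 203 and 309, and 96 and 231 of the main genes were shared. Of the main 326 genes, 1 gene other than Krt19, not named here, was at least 2-fold higher on the germ-free array there. Krt19 reversed to 0.69 with the local background, and the cause was not tested. Ptprc, Sdhd, Pgk1, Gzma and Gsta3, under 2-fold in the main values, changed sign there, and Acta2, Batf, Birc5, Cd83, Chac1, Cyp2c55, Cyp2e1, Defa24, Fn1, Pigr, Pla2g2a, S1pr1 and Zeb1 were under 2-fold. With median scaling Batf, Ccr7, Cd83, Ets1 and Zeb1 were under 2-fold. Of 125 named genes, 21 crossed the 2-fold limit with the deposited table, 18 with the local background, 17 with plain subtraction and 8 with median scaling.

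List medians that crossed a percentile limit were as follows, and the cause was not tested. With the local background, eosinophil and mast cell genes were at 0.033, T cell activation genes at 0.13 and antimicrobial genes at -0.054, all inside the limits. Antimicrobial genes were also inside among genes with levels above the median (-0.36). With 75th percentile scaling their median was 0.018, which still lay below the 0.12 of all genes under that scaling. Outside the limits came goblet genes with plain subtraction (-0.33), offsets of 16 (-0.24) and 0 (-0.33), the deposited table (-0.47), no filter (-0.10) and the brightest probe (-0.10). So did neutrophil genes with 75th percentile scaling (0.00) and no filter (-0.056), and Toll-like receptor genes with subtraction (-0.37) and an offset of 0 (-0.25). Circadian genes did with subtraction (-0.34), an offset of 0 (-0.29) and the table (-0.32), and chemokine genes with subtraction (-0.31), an offset of 0 (-0.19) and the brightest probe (-0.094).

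No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. Neutrophil, endothelial and short-chain fatty acid lists had too few genes above the median level for a value there. Signal over background limits dim genes: median spot intensities of 84.4 and 88.6 lie near the 58.7 and 59.6 of BLANK spots.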

Other observations

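The scan of gene families and the tests on scaling, leukocyte share, epithelial share and T cell share were chosen after the results were seen, while the tests on naive T cells and crypt-base cells were written before the values of their genes were seen, except that the comparisons of the naive list with other T cell lists came after. Antibody variable genes were higher on the specific pathogen-free array as families. Of 28 detected Ighv genes, which encode heavy chain variable segments, 23 were at least 2-fold higher there (median log2 difference -1.77), as were 21 of 25 Igkv genes of the kappa light chain (median -1.70). Gasdermin C genes followed, 4 of 5 (median -2.72), and annexins, 4 of 11 (median -0.68). On the germ-free array, 4 of 8 Gimap genes, GTPases of lymphocyte survival, were at least 2-fold higher (median 1.06), as were 5 of 10 Gbp genes, interferon-induced GTPases (median 1.05). All 9 detected Defa genes, Paneth cell defensins, lay toward germ-free, 3 by at least 2-fold (median 0.48). These came from a scan of 516 families. Of the families, 30 lay at or below the lower and 29 at or above the upper percentile limit. Sets of randomly drawn genes would give 25.8 in all, although members of 1 family may move together. The named families kept their direction under median, 75th percentile and loess scaling and the deposited table. Their medians with the local background are not reported here. Similar sequences within the antibody, gasdermin and defensin families leave open how far their probes are independent.

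Epithelial markers were higher on the specific pathogen-free array, by a list median of -0.92. The values argue against scaling between the arrays as the cause, since the value nearest to 0 under other scalings was -0.99. More crypt-base cells are not excluded. The crypt-base list did not stand apart, with a median of 0.04 at percentile 60.0 (10.5 under median scaling). Surface genes had a median of -0.11 at percentile 3.05. Of the 13 crypt-base genes, 7 lay toward germ-free and 6 toward specific pathogen-free, and 3 had a mean signal under 25. Without a gap to the epithelial list, these values cannot decide the question. A lower leukocyte share alone would move the other cell types alike. Endothelial, glial and red blood cell genes lay 0.97 above the epithelial list (95% bootstrap interval over genes 0.66 to 1.52). Their intervals were above 0 in 6 of 6 comparisons (main, without the offset and deposited values, each with all and with brighter genes). This argues against that explanation for these genes, but only 4 of the 11 had a mean signal of at least 25 (0.94 to 1.76). The leukocyte lists parted too, T cell from macrophage genes by 0.86 (0.33 to 1.24). Fibroblast and smooth muscle genes, of which 15 of 19 were that bright, lay 0.45 above the epithelial list. Their intervals were above 0 in only 2 of 6, so a lower leukocyte share is not excluded. A larger epithelial share cannot be told apart: goblet, Paneth and enteroendocrine genes lay 0.81 above the epithelial list (0.33 to 1.40), but 2 of the 6 intervals included 0. All 13 crypt-base genes and 12 of 14 surface genes lay within 2-fold, though brighter surface genes had a median of -0.38 (percentile 0.815). The gaps of these lists to the epithelial list were not tested. A larger epithelial share, through the isolation or the microbiota, and changed expression within cells may both contribute, which 1 array per group does not separate.

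Type I interferon genes were higher on the germ-free array, by a list median of 1.16. Scaling does not account for it: the value nearest to 0 under other scalings was 1.02. A larger share of T cells cannot be told apart from a change within cells: the interferon list lay 0.56 above the T cell list with an interval of -0.04 to 1.14, while the other 5 of the 6 comparisons had intervals above 0 (0.16 to 1.51 in the deposited values). The absence of the microbiota, or another exposure of the animals, may contribute and was not tested.

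Cell cycle genes were higher on the specific pathogen-free array, by a list median of -0.56, and scaling did not remove this (nearest value to 0, -0.45). Their median lay 0.36 above the epithelial one (interval -0.21 to 0.90), and in the deposited values the gap was -0.01 (-0.84 to 0.93) with all genes and 0.51 (-0.93 to 1.16) with brighter genes, with intervals that included 0 in 6 of 6 comparisons. A larger epithelial share therefore cannot be told apart from a change in cell division, in epithelial or immune cells, to which the microbiota may contribute and which was not tested.

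A hypothesis on the T cell genes is that the germ-free sample held more naive and recirculating T cells. A list of such genes, fixed before its values were seen and before the family scan, with which it shares Gimap4 and Gimap6, had 6 of 17 at least 2-fold higher on the germ-free array and 2 lower (Ly6c1 -1.95, Atp1b1 -1.34), with a median of 0.56 at percentile 100 of random lists. Lef1, a factor of naive T cells, had signals of 166 and 39.3. Genes of tissue-resident T cells had a median of -0.07 (percentile 3.24), or 0.01 under 75th percentile scaling, where that of all genes was 0.12. The naive list lay 0.62 above them (interval 0.20 to 1.36, and 0.34 to 1.92 for brighter genes), with intervals above 0 in 6 of 6 comparisons. This speaks against an equal rise of naive and tissue-resident genes. It does not settle the question, since 9 of the 17 tissue-resident genes had a mean signal under 25. The brightest of them, Rgs1, Rgs2, Plac8 and Ramp3, may also come from other cells. Intervals were above 0 in 5 of 6 comparisons with the cytotoxic and 1 of 6 with the regulatory T cell list. Both fall short of 6 of 6, so an equal rise with those cells is not excluded. The naive list did not separate from the general T cell list (difference -0.04, interval -0.64 to 0.77), so the hypothesis cannot be told apart from more T cells of other kinds as well, which lymphoid tissue or blood carried along in the isolation might also give and which was not tested.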
